A study of Homo sapiens with 509 samples.

How the data were processed

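RNA was measured in K562, a suspension line derived from chronic myeloid leukaemia, and in BJ, a line of human foreskin fibroblasts. Per the labels, 350 libraries came from single K562 cells, 152 from single BJ cells, 3 from K562 RNA prepared in tubes and 4 from BJ RNA prepared in tubes. The series description states 352 K562 and 150 BJ cells and 4 K562 and 3 BJ tubes, and the labels of the single libraries were followed. Cells were captured on a microfluidic circuit, lysed, reverse transcribed and amplified as full-length cDNA by template switching, and libraries were made by tagmentation and sequenced on an Illumina NextSeq, per the labels' protocols. The protocol names no molecular identifiers, so reads were taken as not independent molecules.

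The submitters' processing notes name RSEM, TopHat2, Bowtie, Bowtie2 and the genome build hg19, with no role or order, and the versions they used are not given here because they could not be read with certainty. The tube table and the BJ cell columns held expected counts per gene, as the authors deposited them, and these were rounded to whole numbers before any count test. The K562 cell columns deposited in the same table as the BJ cells held TPM. Each of their totals lay between 998582 and 999920, against 108085 to 2214225 in the BJ cells, and a median of 0.97% of their values above 0 were whole numbers when rounded to 2 decimals, against 73.4% in the BJ cells. Low K562 values multiplied by transcript length fell on 1 or 2 whole steps for 70.3% of values, against 22.4% with shuffled lengths. The size of a step was set in each cell with the unshuffled lengths and not set anew, which favours the first share. Lengths were learned from these steps with a tolerance of 0.06. A count test had been planned for all comparisons before the data were examined, and comparisons with K562 cells were therefore tested with limma on log2(TPM + 1). The gene lists, the rule for named genes, the designs and most of the other settings tried were fixed before the data were examined.

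For those comparisons the BJ cell counts and all tube counts were converted to TPM. Lengths were those of the longest GENCODE transcript with a RefSeq link (GRCh38 annotation, used for lengths only), reduced by 130 bases, the median offset learned from the steps of the K562 values, with a floor of 100 bases. Lengths were found for 22099 genes, and 1510 genes without one were left out of converted tables. Where one gene's transcripts differ in length, this conversion can shift its ratio between cells and tubes, and the log2 ratio of learned over reference length had an SD of 0.43 over 7188 genes with a learned length. No coordinates were used. The tubes had values for 23732 features and the cells for 23704. Of the 28 found only in the tubes, 26 were SEPT, MARCH and MARC genes. The 95 spike-in sequences (92 ERCC) were left out of library sizes and tests, and the mitochondrially encoded genes were not among the features.

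The 3 K562 and 4 BJ tubes were compared with edgeR's quasi-likelihood test on counts (TMM, filterByExpr by group, Benjamini-Hochberg adjustment, threshold 0.05). Cells were not treated as replicates. Each tube's label names the runs it accompanied, and cells were averaged over those runs, giving 3 K562 sets (runs 1 to 3, 132 cells; runs 4 to 6, of which 2 runs had cells, 86 cells; runs 7 to 9, 132 cells) and 1 BJ set (runs 14 to 17, 152 cells). The sets of K562 were compared with the BJ set and with the K562 tubes, and the difference between the lines was compared between cells and tubes as an interaction, all with limma at a mean of at least 1 TPM in a group, with TMM factors. In the first of these the lone BJ set was assumed to vary like the K562 sets, and in the interaction like the K562 sets and the tubes. The summed BJ cells were compared with the BJ tubes with edgeR, an addition made after the units were seen.

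The labels pair each K562 set with the tube that names its runs. Deviations from the group means correlated across genes by 0.15 (runs 1 to 3), 0.02 (runs 4 to 6) and 0.23 (runs 7 to 9). The paired value is given beside a result where it moved a count by over 1.5 times.

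Gene lists (29, of which 28 had a tested gene in the tubes) were tested with camera at a preset correlation of 0.01 and with an estimated correlation, with fry beside them, and called members were also counted with p-values adjusted over the list alone. Camera was run on lists of at least 3 tested genes. Named genes were the 6 largest called changes in each direction with group values that did not overlap and a mean of at least 100 CPM or TPM in the higher group, and the 2 to 4 members of each list with the highest mean. Some genes that this rule takes are not reported here. A fold against a group at 0 counts was computed against 3 counts over the group (0.427 CPM in the K562 tubes, 0.880 CPM in the BJ tubes). Shares of cells above 0 have Wilson 95% intervals. Where 0 cells had a value, the limit given is 3 cells over the number of cells, which bounds cells with a read and not cells that express the gene. Coefficients of variation between cells were taken for genes with a mean of at least 50 TPM, and set against a lowess curve (fraction 0.3) over mean level. BJ cells were also thinned to 500000 reads, which 137 cells reached. The K562 values could not be thinned.

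Steps were tested on simulated data with genes changed by known amounts. In the tube comparison 14.7%, 69.7% and 98.5% of genes changed by a log2 of 1, 2 and 4 were called (8495 genes, false share 6.92%). For K562 sets against BJ the shares were 0%, 20.0% and 51.5% (11196 genes, false share 0%), for K562 sets against K562 tubes 41.2%, 80.3% and 95.5% (10847 genes, false share 4.00%), and for the BJ sum against the BJ tubes 4.40%, 28.8% and 84.8% (8732 genes, false share 16.1%). In these simulations the lone BJ set was made to vary like the K562 sets, and the lone BJ sum like the BJ tubes. The K562 tubes set against K562 sets were also made to vary like the sets, and not by their own spread. These assumptions were therefore not tested, and the false shares do not cover their failure. No cell columns were identical, and replicate tubes differed by more than sampling noise (chi-square per degree of freedom 6.23 to 25.0). Doublets were not called. The highest sum of the other line's 12 or 14 fixed markers was 6.54% of that line's median in a K562 cell and 1.64% in a BJ cell.

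Other settings included DESeq2, RLE or total scaling, no filter, a test against a fold of 2, other pseudocounts, lengths learned from the K562 values, no length conversion, sums per run, pairing and leaving out each set or tube. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.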

Results

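Gene expression was measured in K562, an erythroleukaemia-like suspension line from chronic myeloid leukaemia, and in BJ, an adherent fibroblast line from foreskin. The series title names rank-based differential expression of single cells, and 350 K562 and 152 BJ cells were set beside bulk RNA of the same lines prepared in tubes (3 K562 and 4 BJ libraries). Tube libraries held 2156384 to 2606126 counts in K562 and 732672 to 1162521 in BJ. BJ cells held 108085 to 2214225 counts, and the depth of the K562 cells, deposited as TPM, was estimated from their low values as 120193 to 1043566 reads (median 653851). The 8 K562 and 4 BJ capture runs did not overlap, so line and run cannot be told apart. The labels do not say that tubes or runs came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Intervals and floors cover counting error only.

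The tubes addressed how bulk RNA of the lines differed. The gene furthest above BJ in K562 tubes was a fetal globin gene, which encodes part of the oxygen carrier of fetal red cells. HBG2 stood at 6449 CPM ± 507 (SD, n = 3) and HBG1 at 4603 CPM ± 313, with 0 counts in the 4 BJ tubes. They were at least 7329-fold and 5231-fold higher, and the split between these near-identical genes is uncertain. The cancer-testis antigens PRAME (2966 CPM ± 102) and GAGE4 (893 CPM ± 125, a member of a near-identical family and therefore uncertain), the erythroid ammonium channel component RHAG (1043 CPM ± 26.0) and the retinoic acid synthesising enzyme ALDH1A2 (692 CPM ± 42.8) were at least 3370-fold, 1015-fold, 1185-fold and 787-fold higher. All 20 globin and erythroid genes tested were higher, 20 when adjusted over the list alone. By camera the adjusted p was 5.88e-35, and adjusted p = 0.0201 with an estimated correlation. The median log2 fold change was 10.52, or 7.40 with genes at 0 counts at their bound. Of 13 pan-haematopoietic genes 10 were higher, 10 adjusted over the list alone. The adjusted camera p was 2.13e-07, and adjusted p = 0.0201 with an estimated correlation. Among them were the actin-bundling protein LCP1 (at least 647-fold) and the tetraspanin CD53 (at least 124-fold). Both megakaryocyte genes tested were higher, 2 adjusted over the list alone: NFE2, a globin and platelet gene activator, by 466-fold (95% counting interval 159 to 2257) and the platelet tubulin TUBB1 by 39.0-fold (10.8 to 322). The fitted log2 difference of NFE2 was 8.71, and 9.74 without BJ tube 3. TUBB1 lost its call against BJ tube 2 alone.

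BJ tubes were marked by genes of matrix and adhesion. FSTL1, a secreted glycoprotein, stood at 3808 CPM ± 1740 (SD, n = 4) in BJ and 0 counts in K562, at least 8925-fold lower in K562. The caveolar coat protein CAV1 (1909 CPM ± 79.0), the fibrillar collagen COL3A1 (1623 CPM ± 1044), the semaphorin receptor NRP1 (1599 CPM ± 233), the nitric oxide pathway enzyme DDAH1 (1030 CPM ± 306) and the Wnt inhibitor DKK1 (984 CPM ± 516) were at least 4475-fold, 3805-fold, 3747-fold, 2415-fold and 2307-fold lower. Of 25 extracellular matrix genes 24 were lower in K562, 25 adjusted over the list alone. Tested with camera, the adjusted p was 4.25e-32, and adjusted p = 0.0164 with an estimated correlation. The median was −10.14, or −8.58 with bounds. The type I collagen chain COL1A2 (9433 CPM ± 2708 in BJ, 1.45 CPM ± 1.45 in K562) was 6237-fold lower, on 10 counts in K562, and fibronectin (FN1) 163-fold lower. The fitted log2 difference of COL1A2 was −12.61, −11.96 without K562 tube 1 and −13.56 without K562 tube 3. All 16 fibroblast surface and regulator genes were lower, 16 adjusted over the list alone (camera adjusted p = 1.8e-20, and adjusted p = 0.0155 with an estimated correlation; median −9.67, or −7.46 with bounds), such as the receptor kinase AXL by 142-fold and the hyaluronan receptor CD44 by 150-fold. Matrix proteases and secreted signals were lower for 17 of 18 genes, 17 adjusted over the list alone (camera adjusted p = 5.92e-12, and adjusted p = 0.0164 with an estimated correlation; median −9.03, or −6.76 with bounds), including the gelatinase MMP2, at least 1273-fold. Actin and adhesion genes were lower for 19 of 23, 20 adjusted over the list alone. Camera gave an adjusted p of 2.33e-17, but adjusted p = 0.0654 with an estimated correlation. The integrin chain ITGB1 was 10.5-fold lower.

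**Figure D1:**
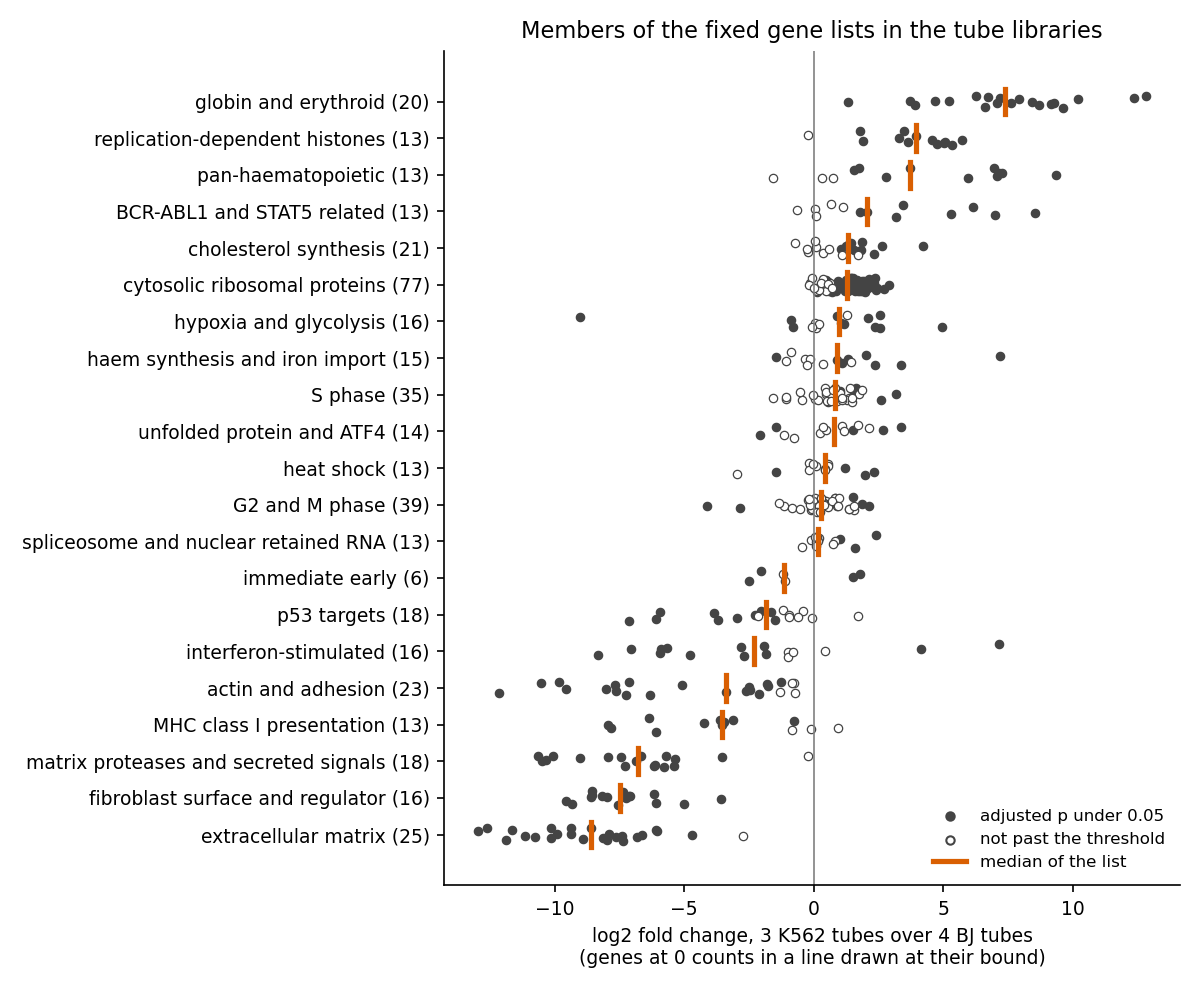
Log2 fold change of each tested member of the fixed gene lists, 3 K562 tubes over 4 BJ tubes, with members called by edgeR marked apart and genes at 0 counts in a line drawn at their bound. Erythroid members lie on the K562 side (median 7.40) and extracellular matrix members on the BJ side (median −8.58).

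Genes of signalling, chromatin, translation and metabolism were also counted by list. Of 13 genes related to BCR-ABL1, the fusion kinase of chronic myeloid leukaemia, and its target STAT5, 8 were higher in K562, 8 adjusted over the list alone. By camera the adjusted p was 1.22e-06, but adjusted p = 0.0915 with an estimated correlation. Among the higher genes were the adaptor CRKL (4.16-fold), STAT5A (128-fold, on 10 counts in BJ) and the cyclin CCND2 (410-fold, counting interval 140 to 1987). The fitted log2 difference of STAT5A was 7.00, and 8.02 without BJ tube 1. That of CCND2 was 8.54, and 12.18 without BJ tube 4, which held its only BJ counts, so that the latter is no bound. Histone genes, which are near-identical and therefore uncertain, were higher for 12 of 13, 12 adjusted over the list alone (camera adjusted p = 7.07e-07, and adjusted p = 0.0178 with an estimated correlation; median 4.56, or 3.94 with bounds). Ribosomal protein genes were higher for 61 of 77, 64 adjusted over the list alone. The adjusted camera p was 4.77e-14, but adjusted p = 0.340 with an estimated correlation. Their median was 1.28. Cholesterol synthesis genes were higher for 12 of 21, 13 adjusted over the list alone. Tested with camera, the adjusted p was 0.00135, but adjusted p = 0.348 with an estimated correlation. Examples were the squalene synthase FDFT1 (3.65-fold) and the sterol isomerase EBP (6.27-fold). Their list mean stood at 6.22, 5.36, 5.10 and 6.34 in mean log2(CPM + 1) in BJ tubes 1 to 4. Haem synthesis and iron import genes were higher for 7 and lower for 1 of 15, with 7 and 2 adjusted over the list alone. Camera gave an adjusted p of 0.0146, but adjusted p = 0.340 with an estimated correlation. The haem enzyme UROD was 4.04-fold higher. Hypoxia and glycolysis genes were higher for 8 and lower for 3 of 16, the same numbers adjusted over the list alone (camera adjusted p = 0.0904, and 0.0228 without K562 tube 3), with the glycolytic enzymes ALDOA 2.09-fold higher and GAPDH 1.72-fold lower.

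Lists of immune, damage-response and cell cycle genes are given with their values in each BJ tube. Of 13 genes of MHC class I presentation 10 were lower, 10 adjusted over the list alone. By camera the adjusted p was 0.00135, but adjusted p = 0.340 with an estimated correlation. The antigen-presenting chain HLA-E was 11.1-fold lower. Of 18 p53 targets 10 were lower, 11 adjusted over the list alone. The adjusted camera p was 0.00135, but adjusted p = 0.340 with an estimated correlation. The cell cycle inhibitor CDKN1A was 141-fold and the p53 ligase MDM2 7.74-fold lower. Interferon-stimulated genes were lower for 10 and higher for 2 of 16, the same adjusted over the list alone. Tested with camera, the adjusted p was 0.0395, but adjusted p = 0.617 with an estimated correlation, 0.0861 without BJ tube 1 and 0.238 without BJ tube 4. The membrane protein IFITM1 was 17.4-fold higher. S phase genes were higher for 6 of 35, 2 adjusted over the list alone. Camera gave an adjusted p of 0.0117, but adjusted p = 0.718 with an estimated correlation, 0.0574 without BJ tube 1 and 0.0625 without BJ tube 4. The replication factor CDC45 was 9.01-fold higher. G2 and M phase genes were higher for 3 and lower for 2 of 39, the same adjusted over the list alone (camera adjusted p = 0.0904, 0.00716 without BJ tube 2 and 0.0146 without BJ tube 3). Mean log2(CPM + 1) of the G2 and M phase list was 5.55, 7.60, 7.47 and 4.05 in BJ tubes 1 to 4, against 6.97 to 7.22 in the K562 tubes, and that of the S phase list 4.55, 6.38, 6.97 and 3.70, against 6.71 to 6.82. The p53 list stood at 5.58, 4.96, 4.55 and 5.90 in the same tubes, MHC class I at 5.85, 5.36, 4.69 and 6.12, interferon-stimulated genes at 5.04, 4.17, 3.85 and 5.51, and extracellular matrix at 7.43, 7.04, 6.90 and 7.69. Without BJ tubes 1 and 4, chosen after these values were seen, S phase genes were higher for 4 and lower for 6 of 36 and G2 and M phase genes higher for 4 and lower for 12 of 39 (camera adjusted p = 0.634 and 0.0938), and interferon-stimulated genes had a camera adjusted p of 0.397.

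**Figure D2:**
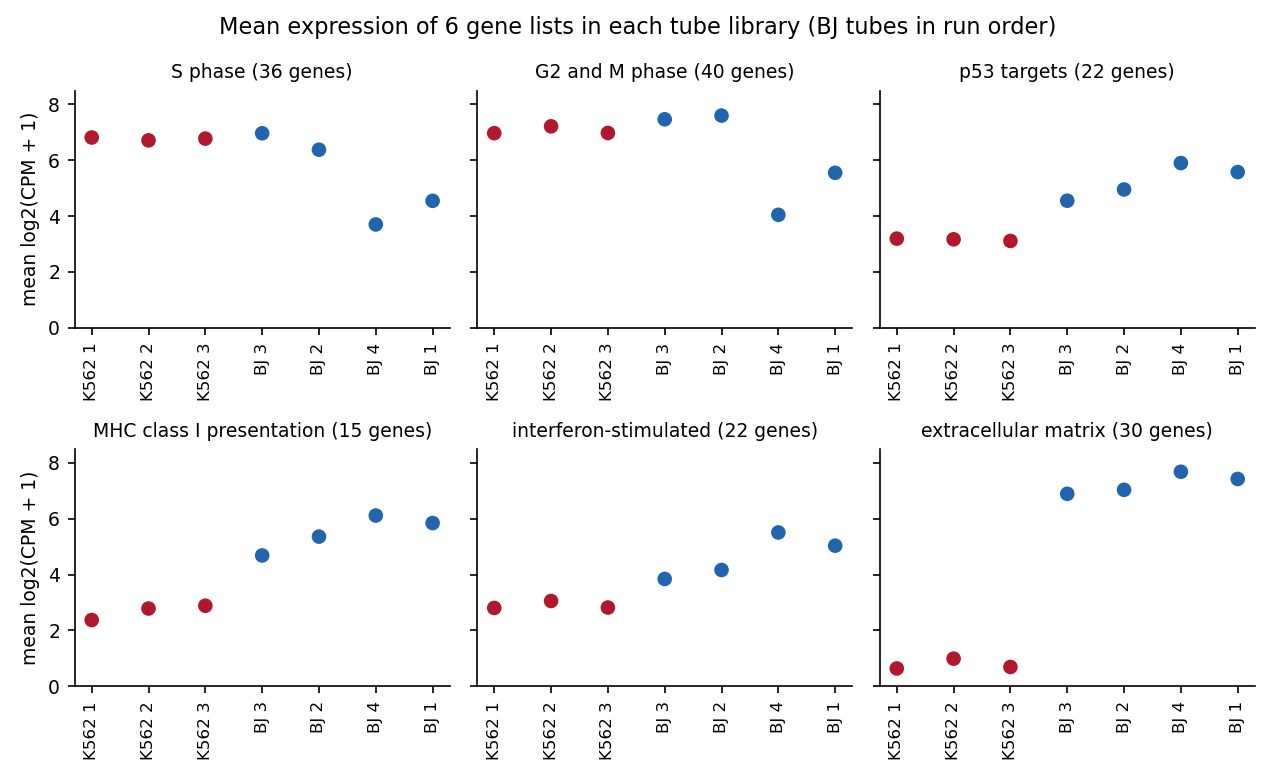
Mean log2(CPM + 1) of selected gene lists in each of the 3 K562 and 4 BJ tubes, each point being 1 library and the BJ tubes standing in run order. The G2 and M phase list ranged from 4.05 to 7.60 among the BJ tubes and from 6.97 to 7.22 among the K562 tubes.

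Other fixed lists gave few calls in the tubes. Heat shock genes were higher for 3 and lower for 1 of 13 (camera adjusted p = 0.384), unfolded protein and ATF4 genes higher for 3 and lower for 2 of 14 (0.406), and spliceosome and nuclear retained RNA higher for 3 of 13 (0.187), with the same counts adjusted over the list alone. Immediate early genes were higher for 2 and lower for 2 of 6, the same adjusted over the list alone, with a median of −1.15 although camera ranked the list on the higher side (adjusted p = 0.995). At chromosome band 9p21, both genes tested were lower, 2 adjusted over the list alone: the ubiquitin ligase adaptor KLHL9 had 0 counts in K562 (at least 254-fold lower) and MTAP, an enzyme of methionine salvage, was 103-fold lower. The only HOX gene tested, HOXA10, was at least 101-fold lower. Among markers of other cell types, the keratinocyte list had 1 gene tested, the desmosomal DSP, at least 113-fold lower in K562, and the endothelial list the receptor TEK, at least 37.4-fold lower. Of lymphocyte and monocyte genes, lysozyme (LYZ) was 18.0-fold and the T cell receptor component CD3D at least 31.2-fold higher. The melanocyte factor MITF was not called (log2 fold change −0.61, SE 0.45). Each of these calls, and that of HOXA10, also stood when adjusted over the list alone. Of mitochondrially encoded genes 0 were tested. Of 21 lists tested by camera 15 passed, and 6 did with an estimated correlation: globin and erythroid, pan-haematopoietic, extracellular matrix, fibroblast surface, matrix proteases and histones. In total edgeR called 3638 of 8929 genes, 1587 higher and 2051 lower in K562, or 2152 against a fold of 2. Scaled by total counts, 1890 were higher and 1843 lower. Against BJ tube 2 alone, the tube whose runs match the BJ cells, 2137 of 10928 were called. That scaling moved the median log2 fold change of all genes from −0.02 to 0.15.

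Single cells addressed the same contrast cell by cell. Fetal globin was present in every K562 cell: HBG1 and HBG2 had a value above 0 in 350 of 350 (95% Wilson interval 98.9% to 100%), with set means of 11768 TPM ± 1337 and 16942 TPM ± 1842 (SD, n = 3 sets), and in 0 and 1 of 152 BJ cells, where 0 allows a share of up to 1.97%. The embryonic globins HBE1 and HBZ were listed above 0 in 94.0% (91.0% to 96.0%) and 70.9% (65.9% to 75.4%) of K562 cells, and ALAS2, the first enzyme of erythroid haem synthesis, in 42.6% (37.5% to 47.8%). PRAME was found in 350 and GAGE4 in 348 K562 cells, and both in 0 BJ cells. In the other direction, DKK1 was found in 149 of 152 BJ cells (98.0%, 94.4% to 99.3%) and 0 of 350 K562 cells (up to 0.857%), CAV1 in 152 and 1, and COL1A2 in 152 and 14. The 9p21 gene KLHL9 was found in 74.3% of BJ cells (66.9% to 80.6%) and 0 K562 cells, and CDKN2A, the cell cycle inhibitor of that locus, in 21.1% (15.3% to 28.2%) and 0.

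Differences between sets were taken on the log2(TPM + 1) scale, which understates low genes. The largest above BJ were HBG2 (14.07, SE 0.23), HBG1 (13.56), GAGE4 (12.13), PRAME (11.09), the alpha globin HBA2 (10.24, near-identical to HBA1 and uncertain) and HBE1 (10.08). Among the largest below were DKK1 (−10.24, SE 0.22), the matrix glycoprotein THBS1 (−9.86), NGFRAP1 (−9.82), CAV1 (−9.77) and COL1A2 (−9.42). Of the erythroid list 24 of 28 genes were higher, 25 adjusted over the list alone. By camera the adjusted p was 2.64e-12, but adjusted p = 0.316 with an estimated correlation. Of the extracellular matrix list 28 of 29 were lower, 28 adjusted over the list alone (3.9e-15, but adjusted p = 0.25 with an estimated correlation). MHC class I genes were lower for 11 of 14, 11 adjusted over the list alone (0.000177, but adjusted p = 0.334 with an estimated correlation), and the 9p21 list for 4 of 4, 4 adjusted over the list alone (0.00349, but adjusted p = 0.316 with an estimated correlation). S phase genes were higher for 12 of 36, 12 adjusted over the list alone (0.00136, but adjusted p = 0.517 with an estimated correlation). G2 and M phase genes were higher for 1 and lower for 9 of 40, with 1 and 7 adjusted over the list alone (0.0121, but adjusted p = 0.493 with an estimated correlation). Of 28 lists 20 passed camera, and 0 with an estimated correlation. Limma called 4868 of 13108 genes, 2065 higher and 2803 lower, with 3 K562 sets against 1 BJ set and no BJ spread of its own. The count was 2070 (621 higher and 1449 lower) without the set of runs 1 to 3, 1784 (453 and 1331) without runs 4 to 6, 3243 without runs 7 to 9, 2124 against a fold of 2, and 8324 with runs in place of sets. The count with runs takes the 8 K562 and 4 BJ runs as independent, although they form 3 sets and 1 set. Scaling by totals moved the median of all genes from −0.02 to −0.17.

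The differences between the lines in cells and in tubes were then set side by side. Fold changes of 8727 genes correlated by a Spearman coefficient of 0.830 across genes, which are not independent replicates. Of 3537 genes called in the tubes, 3412 (96.5%) had the same direction in the cells, 2356 were called in the same direction and 24 in the opposite direction. Of those 24, the 13 with a higher value in cells had a median transcript length of 7289 bases and the 11 with a lower value 1337 bases. Examples, chosen after their values were seen, were DCUN1D5, a neddylation factor (1.61 in tubes, −2.37 in cells), and the mitochondrial ATP synthase gene ATP5A1 (−0.59 and 1.45). Ranking genes by the rank statistic of K562 against BJ cells found the tube calls with an area under the curve of 0.836 (8730 genes, 3539 called), against 0.832 for the ratio of means. For tube calls against a fold of 2 the rank statistic gave 0.855 and the ratio of means 0.919. With 10, 25, 50 and 100 cells per line it averaged 0.745, 0.792, 0.816 and 0.828 over 20 draws, and with 1 run per line 0.794 (0.771 to 0.812 over 32 pairs). The rank statistic lay beyond 0.75 or 0.25 for 2133 genes between the lines, for 102 to 250 between K562 sets and for 11 to 69 between BJ runs.

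**Figure D3:**
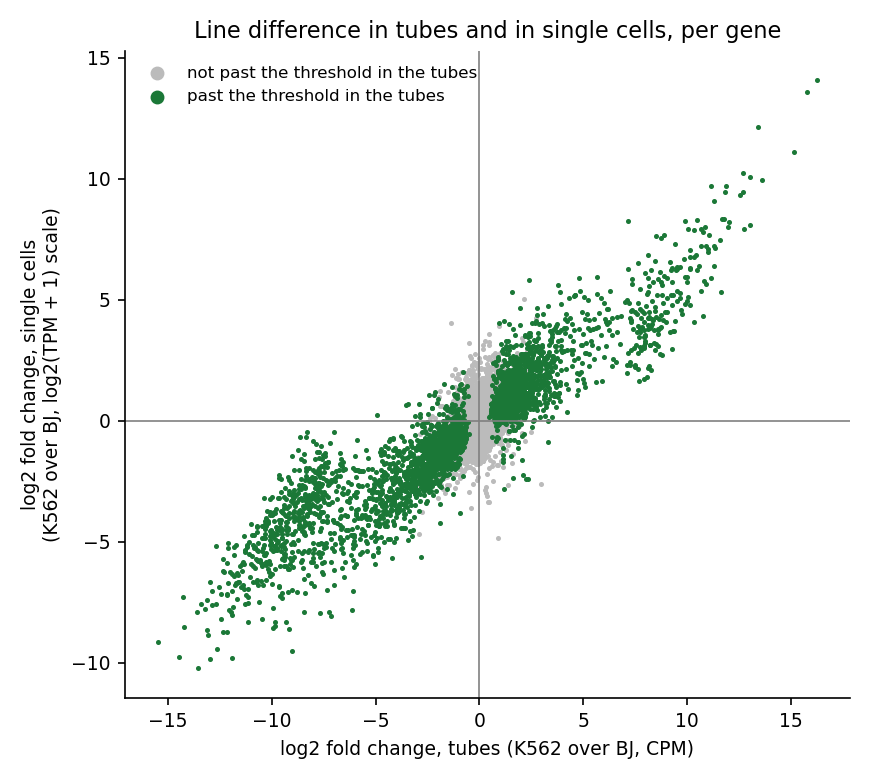
Log2 fold change of K562 over BJ in single cells (log2(TPM + 1) scale) against that in tubes, each point being 1 gene and colour showing whether it was called in the tubes. Most genes called in the tubes share their direction in cells (96.5%).

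K562 cells were compared with K562 tubes to see what the preparation changed. Immediate early genes, which are induced within minutes of a stimulus, were higher in cells. EGR1 stood at 1248 TPM ± 134 in the sets and 68.6 TPM ± 18.1 in the tubes (n = 3 each; log2 difference 4.04, SE 0.20, limma adjusted p = 4.41e-06), and FOS at 559 TPM ± 171 and 30.6 TPM ± 8.44 (3.99, SE 0.25, adjusted p = 1.22e-05). Of 20 immediate early genes 11 were higher in cells and 0 lower, 15 adjusted over the list alone. The adjusted camera p was 6.65e-08, but adjusted p = 0.441 with an estimated correlation. The median was 1.83, and 14 had every set above every tube, which chance gives a gene in 5% of cases. Beside EGR1 and FOS, the largest differences under the rule for named genes were RPS29 (4.99), C12orf45 (4.71), the mitochondrial superoxide dismutase SOD2 (3.88) and FGF13 (3.53) above the tubes, with reference lengths of 7062 to 23529 bases. Below the tubes were LUZP6 (−5.48), PIGY (−4.46), GAGE12D (−4.32), NAA38 (−4.13), DCUN1D5 (−3.67) and MCTS1 (−3.58), with lengths of 177 to 1337 bases. PIGY stood at −5.08 without K562 tube 2. These sizes rest on the lengths used, since only the tube counts were converted. Without conversion, which mixes units, RPS29, C12orf45, SOD2 and FGF13 stood at 3.63, 1.91, 1.65 and 0.788. The genes below the tubes then stood, in the same order, at −0.769, 0.235, −1.656, −2.546, −2.571 and −2.185. The G2 and M phase list was lower, with 2 of 40 genes called, 1 adjusted over the list alone (median −0.41, camera adjusted p = 6.41e-05, but adjusted p = 0.681 with an estimated correlation). Spliceosome and nuclear retained RNA genes were higher for 7 and lower for 0 of 13, with 7 and 2 adjusted over the list alone and a median of 1.29, such as the splicing factors SRSF3 (1.29) and SRSF6 (1.58), while MALAT1, a nuclear RNA, had 0.43 and was not called. As a list they did not pass camera (adjusted p = 0.0601, and adjusted p = 0.681 with an estimated correlation), while fry, which does not compare a list with other genes, gave an adjusted p of 0.0107. Limma called 1254 of 11586 genes, 862 higher and 392 lower, or 1146 and 301 when scaled by totals, which moved the median of all genes from 0.11 to 0.25. Of 25 lists only the immediate early and the G2 and M phase lists passed camera, while fry passed the immediate early, spliceosome, actin and adhesion, p53, HOX, melanocyte, and lymphocyte and monocyte lists, and not the G2 and M phase list. Pairing each set with its tube gave 1911, a test against a fold of 2 gave 108, and leaving out the set of runs 1 to 3, 4 to 6 or 7 to 9 gave 467, 380 or 637.

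**Figure D4:**
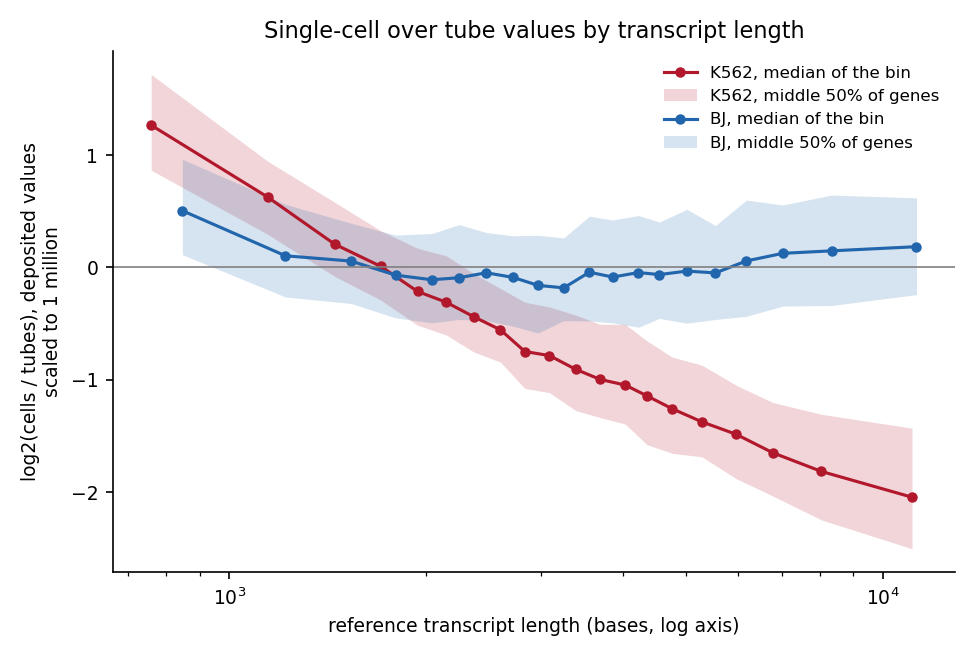
Median log2 ratio of deposited values, scaled to equal totals, in cells over tubes, with the middle 50% of genes shaded, in 20 bins of reference transcript length (bases, log axis), for K562 and BJ. The K562 ratio falls from 1.27 at 759 bases to −2.04 at 11075 bases. The BJ ratio lies at 0.51 at 847 bases, −0.18 at 3247 bases and 0.19 at 11251 bases.

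BJ cells and BJ tubes, both held as counts, gave 0 calls by edgeR among 9462 genes, with 522 at an unadjusted p under 0.05, and 16 of 3123 by DESeq2. EGR1 stood at 978 CPM in the summed cells and 37.3 CPM ± 24.5 in the tubes (SD, n = 4; log2 difference 4.70, SE 0.63, edgeR adjusted p = 0.594), and FOS at 344 CPM against 10.2, 244, 1.14 and 28.2 CPM in tubes 1 to 4. Of 15 immediate early genes 0 were called, 5 adjusted over the list alone. Tested with camera, the adjusted p was 5.46e-12, but adjusted p = 0.190 with an estimated correlation. Their median was 2.63, and 12 lay above all 4 tubes. Of 21 lists 5 passed camera and 0 with an estimated correlation. Ribosomal protein genes had a median of 0.50 with 0 of 77 called, 1 adjusted over the list alone. Camera gave an adjusted p of 5.48e-08, but adjusted p = 0.751 with an estimated correlation. Actin and adhesion genes (median 0.34, 0 of 25 called, 8 higher and 2 lower adjusted over the list alone) had a camera adjusted p of 0.0308, but adjusted p = 0.697 with an estimated correlation. The G2 and M phase list had a median of 0.54 with 0 of 39 called, 0 adjusted over the list alone (camera adjusted p = 0.00192, but adjusted p = 0.816 with an estimated correlation). The 4 named members lay above tubes 1 and 4 and below tubes 2 and 3, of which tube 2 matches the runs of the cells. TOP2A stood at 723 CPM in the summed cells and 300.8, 1070.5, 979.7 and 35.2 CPM in tubes 1 to 4, and CCNB1, ANLN and BIRC5 at 600.1, 498 and 596 CPM in the cells and 756, 701 and 702 CPM in tube 2. The spliceosome list had 0.43 with 0 of 13 called, 1 adjusted over the list alone (camera adjusted p = 0.00192, but adjusted p = 0.334 with an estimated correlation). Against the positive medians, the 4 ribosomal protein genes with the highest means were lower in cells (RPL3 −0.534, RPLP0 −0.104, RPL4 −0.503 and RPL15 −0.301). So were the 4 such actin and adhesion genes (ITGB1 −0.868, CAV1 −0.405, TPM2 −0.788 and VCL −1.094). Scaling by totals moved the median of all genes from −0.07 to 0.07. The sum of cells is 1 library. With counts summed per run 1402 of 12561 genes were called, which takes the 4 runs of 1 set as independent.

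**Figure D5:**
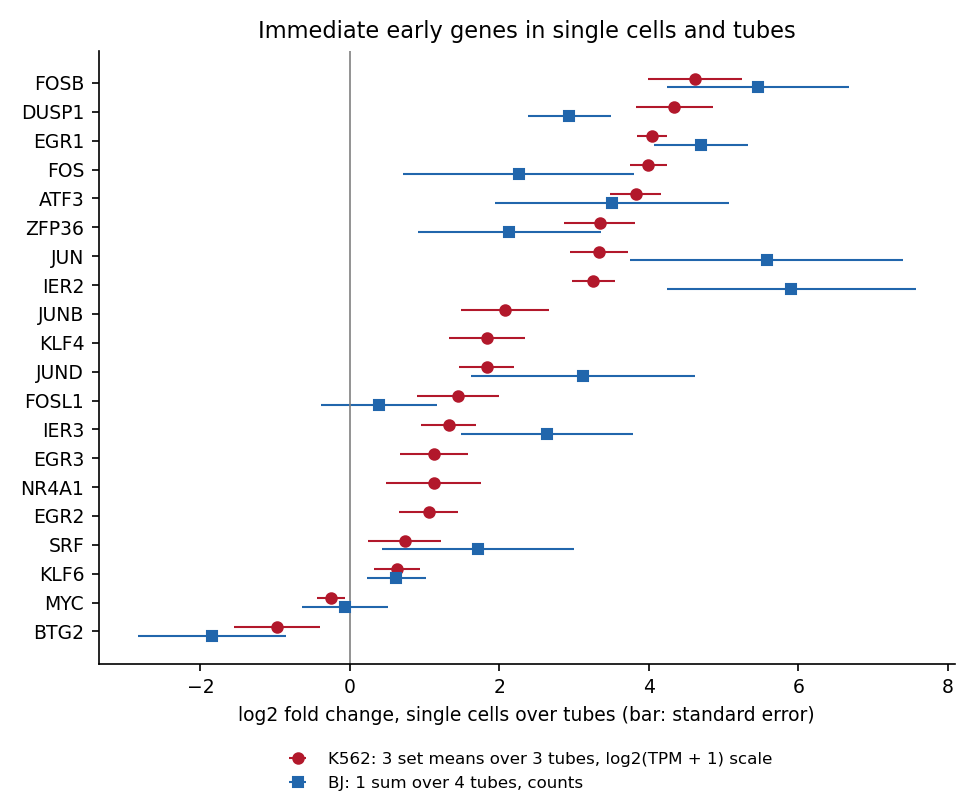
Log2 difference of single cells over tubes for each immediate early gene, in K562 (log2(TPM + 1) scale, 3 sets against 3 tubes) and BJ (counts, 1 sum against 4 tubes), with standard errors. The medians are 1.83 over 20 genes and 2.63 over 15 genes.

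Whether the line difference itself differed between cells and tubes was tested as an interaction. The BJ cells entered as 1 set with no spread of its own, assumed to vary like the other libraries. Sets and tubes were taken as unpaired, and no paired interaction was fitted. Of 13540 genes 76 passed, 39 with a K562 excess greater in cells and 37 with one smaller, or 35 and 50 when scaled by totals. The balance of directions was not held in other settings: 29 and 71 passed without BJ tube 4, 208 and 659 with no filter, 2 and 7 against a fold of 2, and 190 and 47 without length conversion. RPL14, a ribosomal protein gene, stood at 1612 TPM in K562 cells, 109 TPM in BJ cells, 234 TPM in K562 tubes and 140 TPM in BJ tubes (interaction 3.20, SE 0.29, adjusted p = 0.00148), and MCTS1, a translation reinitiation factor, at 20.1, 238, 224 and 194 TPM (−3.67, SE 0.34, adjusted p = 0.00148). RPL14 and MCTS1 had reference lengths of 7072 and 1130 bases. Only the K562 cells kept the submitters' lengths, so a wrong reference length would itself shift the interaction. The 39 had a median reference length of 6033 bases and the 37 of 801 bases, against 3061 over all genes tested. After conversion to TPM the line difference in cells minus that in tubes still rose with length, by 0.436 per doubling over 8727 genes. Over the 3410 genes with a learned length it rose by 0.289 with reference lengths and by 0.222 with learned lengths (SE 0.025). Histone genes had a median of −0.89 with 0 higher and 3 lower of 49, 11 adjusted over the list alone. By camera the adjusted p was 1.89e-06, but adjusted p = 0.413 with an estimated correlation. The G2 and M phase list had a median of −1.37 with 0 of 40 called, 0 adjusted over the list alone (9.83e-05, but adjusted p = 0.952 with an estimated correlation). This value rests on all 4 BJ tubes, in which the list mean stood at 5.55, 7.60, 7.47 and 4.05 on the log2(CPM + 1) scale, and BJ tube 2, with 7.60, is the one that matches the BJ cells. Leaving out the K562 set of runs 1 to 3, 4 to 6 or 7 to 9 gave 15, 15 or 17 calls (5 and 10, 5 and 10, or 6 and 11 by direction), leaving out K562 tube 1, 2 or 3 gave 25, 38 or 27, and leaving out BJ tube 2 gave 35 (14 and 21).

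Cells of each line also varied among themselves. K562 cells had a median of 7695.5 genes above 0 (4333 to 9295) and BJ cells 7992.5 (5987 to 9430), and BJ cells thinned to 500000 reads had 7702, a depth the K562 values do not allow. In K562 the genes with most variation for their level included the globins HBZ (coefficient of variation 2.32, mean of 3 sets), HBE1 (1.84), HBA2 (1.39), HBG2 (0.903) and HBG1 (0.838), with ALAS2 at 2.61. In BJ they included the S phase histone gene HIST1H4C (1.64, mean of 4 runs), the chemokines CCL2 (2.71) and CXCL1 (2.27), the collagenase MMP1 (2.58), found in 34.9% of cells (27.8% to 42.7%), and the metalloprotease inhibitor TIMP3 (2.19). Of the 100 most variable genes, 46 were shared by all 3 K562 sets (0.175 expected by chance) and 53 by all 4 BJ runs (0.00640 expected). In BJ cells thinned to 500000 reads 35 were shared, of which 25 were among the 53. The thinned cells were taken in CPM over 3223 genes and the others in TPM over 2500, so these numbers differ by more than depth. Thinned to 250000 reads, 36 were shared.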

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

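The tests of explanations and the comparison with BJ tube 2 alone in this part were chosen after the result was seen, except the test of the immediate early genes against random lists, while the interaction and leaving out each set or tube were planned. The run-order explanation was narrowed to a steady drift after its value was seen.

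The ratio of deposited values in K562 cells over K562 tubes fell with transcript length, with a slope of −0.784 per doubling (log2), and of −0.696 to −0.887 in the 8 runs. The K562 cell columns holding TPM, which divides by length, may account for this. Of their low values 70.3% fell on whole steps with reference lengths, by which the steps were set, and 22.4% with shuffled lengths. A steady fall with length shared by single-cell preparation of both lines is argued against by the BJ slope of −0.026. That slope does not exclude an uneven length effect. Medians of BJ length bins stood at 0.51 at 847 bases, −0.18 at 3247 bases and 0.19 at 11251 bases. After conversion an opposite trend was left in the line difference in cells minus that in tubes, of 0.436 per doubling over 8727 genes. Over 3410 genes it stood at 0.289 with reference lengths and 0.222 (SE 0.025) with lengths learned from the K562 values. This cannot tell whether wrong lengths were its whole cause. An error left in a learned length enters both the line difference and the length, and so adds to the trend. Lengths were also sought only near the reference length. What leaves this trend stays open. It bears on the interaction calls, of which 29 of 39 above and 0 of 37 below had transcripts of at least 4000 bases.

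Immediate early genes were higher in cells than in tubes of both lines, with medians of 1.83 in K562 and 2.63 in BJ, though camera gave adjusted p = 0.441 and adjusted p = 0.190 with an estimated correlation. The length conversion is argued against by the BJ median of 2.63, which used unconverted counts. A shift shared by genes of the same abundance is argued against too, since the medians lay at percentile 100 of 10000 matched random lists in both lines, whose highest medians were 0.92 and 1.92 and which leave out correlation between members. A response of the cells between harvest and lysis on the chip may account for it, as a hypothesis. Handling and preparation cannot be told apart, because all cells went through the chip and no tube did. The interaction of line and preparation had a list median of 0.06 on the log2(TPM + 1) scale. In the separate fits, on unlike scales, single genes differed between the lines in both directions, with wide errors in BJ. IER2 stood at 3.26 in K562 and 5.90 (SE 1.67) in BJ, and FOS at 3.99 and 2.255 (SE 1.545). In BJ the test called 0 of the genes, and tube 2 alone, which matches the runs of the cells, gave a median of 2.62.

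Cell cycle genes differed between the 4 BJ tubes, by a range of 3.55 in the mean log2(CPM + 1) of the G2 and M phase list and 3.27 in that of the S phase list. Depth is argued against by ranges of 3.78 and 3.44 for these lists after thinning all tubes to 699017 counts, and scaling by ranges of 3.67 and 3.38 with total counts. A steady drift with run order is argued against for the G2 and M phase list by reverse steps of 1.64. For the S phase list the reverse steps were 0.85, under the bound of 1 set for excluding it, so that drift is not excluded there. A step between groups of runs was not tested. No counts of HBG1 or HBG2 were found in BJ tubes, which limits K562 RNA there to 0.037%, a check left out of the weighed explanations after its result was seen. A difference in growth state between the cells of the tubes stays open, as untested. The labels do not say whether these tubes came from separate cultures.

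In the BJ tubes, 6 of 117 values had an extreme tube by Dixon's ratio, where chance gives 5.8 at 1 in 20: the heat shock list (0.843), ribosomal proteins (0.861), the spliceosome list (0.835), KLHL9 (0.909), FOS (0.877) and RPLP0 (0.836). The preparation difference differed between the lines for 76 genes by limma's interaction, the largest being SOD2 (5.05), C12orf45 (4.25), FGF13 (3.65), RPS29 (3.52), RPL14 (3.20) and MED28 (3.11) above, and LUZP6 (−5.65), NAA38 (−4.60), METTL21A (−4.26), GAGE12D (−4.20), MTRNR2L2 (−3.92, a near copy of mitochondrial ribosomal RNA and uncertain) and MCTS1 (−3.67) below. Of these, C12orf45, FGF13, GAGE12D, MED28, RPS29 and SOD2 lost their call without each of the 3 K562 sets in turn, when 15, 15 and 17 genes were called, and SOD2 stood at 4.43 without BJ tube 4. The BJ cells entered this test as 1 set with no spread of its own. Its values also rest on the reference lengths, by which the K562 cells were not converted. Spike-in sequences outside the comparisons took a median of 14.5% of the deposited total in K562 cells and 5.85% in BJ cells. The first is a share of TPM and the second of counts, so they cannot be compared. ERCC sequences summed to more than 3 counts, the limit that a count of 0 allows, in 7 BJ cells and to any count in 8 (highest 29.0), while 1 K562 cell held 1.60 TPM and the tubes 0.

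Of the 35 splits of the 7 tubes into 3 and 4, only 1, the real split, gave 3638 calls. This share of 1 in 35 is the smallest that these splits can give. It argues against chance for that count only if the tubes are taken as independent, which the labels do not state. The highest of the others gave 0. Every other split puts tubes of both lines in 1 group, which adds the line difference to the spread within groups, so their 0 adds nothing to that share. For K562 sets against K562 tubes, 1 of 10 splits gave 1254 and the highest other 0, and 10 splits are too few for a share under 0.05.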

How the results depend on the processing

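Tests without length conversion, with learned lengths or other pseudocounts, with the top 50 or 200 genes, with scaled deposited values, with lists scaled by totals, with BJ tubes left out together and on the BJ sum were added after seeing the data. The tube comparison held its count within 1.5 times under DESeq2 (4659 of 12390), RLE (3630), total scaling (3733), no filter (4373) and leaving out each tube (3115 to 3725), and moved to 2152 against a fold of 2 and 2137 with BJ tube 2 only. Tube numbers shared by the lines do not pair them (correlations −0.01, −0.05 and −0.01), and with the number as a replicate block 3107 genes were called, against 3542 in the same tubes without it. The block of set and tube in K562 moved the count to 1911 and made 8 named genes pass.

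Other counts moved as follows, and the cause was not tested unless fewer samples or a stricter threshold shows it. Counts per run take the runs of a set as independent. K562 cells against BJ cells gave 2124 against a fold of 2, 8324 per run and 1784 to 3243 without each set. K562 sets against tubes gave 108 against a fold of 2, 3780 without length conversion and 380 to 1546 without each set or tube. The BJ sum gave 16 by DESeq2 and 1402 per run. The interaction gave 867 with no filter, 9 against a fold of 2, 115 with a pseudocount of 5, 237 without conversion and 15 to 100 without each set or tube. The correlation of fold changes was 0.895 by Pearson, 0.787 without conversion, 0.841 with learned lengths and 0.812 to 0.828 without each library. Of 21 gene lists, 15 passed camera and 6 with an estimated correlation (14 to 17 without each tube). Genes per thinned BJ cell were 7114 at 250000 reads, 5884 at 5 reads and 7992.5 without thinning. The ranking gave 0.855 for calls against a fold of 2 (0.919 by the ratio of means), 0.807 and 0.801 with deposited values taken as 1 unit, unscaled and scaled, and 0.794 with 1 run per line. Shared variable genes were 24 of 50 and 101 of 200 in K562, and 21 of 50, 89 of 200 and, thinned and in CPM, 35 of 100 in BJ.

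Sign changes of values uncalled in both settings are counted below. Many of the other reversals were of values not called in the main fit. Examples were FTH1 in cells, BIRC5 in tubes, and HBG1, FTL and MALAT1 in K562 sets against tubes. Nearly all of these other reversals were made by leaving out the length conversion, which by construction mixes units. In cells this gave log2 differences of 1.20 for FTH1, 2.13 for CKS2, 1.03 for B2M, 0.447 for IFITM3 and 1.56 for IFITM2. In K562 sets against tubes it gave 0.235 for PIGY, 1.77 for HBG2, 1.73 for HBG1, 1.01 for HBE1, 1.52 for HBA2, 1.61 for FTL, 0.532 for UROD, 0.814 for ARHGDIB, 1.87 for S100A6, 0.962 for TIMP1, 0.478 for HMGB2, 1.46 for CKS1B, 2.35 for CKS2, 1.48 for B2M, 1.67 for IFITM2, 1.92 for IFITM3, 0.770 for TPI1, 0.732 for FDPS, 2.18 for RPS18, 1.02 for RPLP0, 1.40 for HIST1H2BK, 1.26 for HIST1H1C, 2.27 for HIST1H3D, −1.26 for MALAT1 and 1.24 for CD3D, and in the interaction 0.967 for MTRNR2L2. In tubes BIRC5 became −0.74 without BJ tubes 1 and 4 and −0.84 with tube 2 only. There the G2 and M phase list turned lower (camera adjusted p = 0.00471); the cause was not tested. Of the named values under all settings, 1424 in tubes stayed on their side of the threshold, 31 lost and 24 gained a call, and in cells 1267 stayed, 138 lost and 46 gained it. K562 sets against tubes gave 1525, 72 and 42, the BJ sum 845, 0 and 15, the interaction 166, 49 and 0, and gene lists 232, 16 and 3. Among those that stayed, uncalled values changed sign 62 times in tubes, 15 in cells, 62 in K562 sets against tubes, 49 in the BJ sum and 0 in the interaction, such as FOS in tubes (−1.12, and 1.23 without BJ tube 2) and PSAT1 (1.17, and −0.18 without K562 tube 2). DESeq2 on comparisons with K562 cells and sums of thinned cells were not run, because TPM holds no counts, and the cell filter removed 0 cells, so it tested nothing. Depth limits low genes most: in BJ tubes 3 counts are 0.880 CPM.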

Other observations

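The comparison of runs and the check on shared genes and depth in this part were chosen after the values were seen.

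The correlation between genes of a list from cell to cell was compared between the lines. G2 and M phase genes had a mean pairwise Spearman correlation across cells within runs of 0.671 ± 0.0482 in BJ (SD, n = 4 runs) and 0.360 ± 0.0956 in K562 (n = 8 runs), and S phase genes 0.407 ± 0.0488 and 0.191 ± 0.0415. Ribosomal protein genes stood at 0.311 in BJ and 0.164 in K562, and p53 targets at 0.116 and 0.0116. In the other direction, hypoxia and glycolysis genes stood at 0.318 ± 0.0557 in K562 and 0.0132 ± 0.0165 in BJ, cholesterol synthesis genes at 0.266 and 0.0482, and unfolded protein and ATF4 genes at 0.192 and 0.0722. For each of these 7 lists every run of one line lay above every run of the other, with a two-sided exact permutation p of 0.00404, the smallest that 8 against 4 runs can give, and 0.00981 after Benjamini-Hochberg adjustment over 17 lists. Haem synthesis and iron import genes (0.0723 in K562 and 0.0249 in BJ, adjusted exact p = 0.0258) and histone genes (0.140 and 0.216, adjusted exact p = 0.0458) passed too, and 8 lists did not, among them immediate early genes (0.154 in K562 and 0.134 in BJ, exact p = 0.335, adjusted 0.437). These p-values take the runs as independent. The 4 BJ runs form 1 set and the 8 K562 runs 3 sets, so the p-values are too small if runs of a set are alike, and 3 sets against 1 allow no p under 0.05. Line and run cannot be told apart.

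With only the genes measured in both lines, and the BJ cells thinned to 250000 reads, the values were 0.661 in BJ and 0.360 in K562 for G2 and M phase, 0.401 and 0.203 for S phase, 0.384 and 0.164 for ribosomal proteins, 0.083 and 0.007 for p53 targets, 0.004 and 0.342 for hypoxia and glycolysis, 0.042 and 0.256 for cholesterol synthesis, and 0.064 and 0.179 for the unfolded protein list, each with an exact p of 0.00404. Haem synthesis and iron import genes then stood at 0.021 and 0.061 (exact p = 0.0364), and histone genes at 0.213 and 0.229 (exact p = 0.630), no longer lower in K562. The K562 cells could not be thinned, and their values stayed in TPM.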
